A study of Mus musculus with 19 samples.

How the data were processed

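Chromatin of mouse macrophages was profiled by ChIP-seq in 19 libraries. Maf-DKO macrophages had 5 immunoprecipitations (H3K4me1, H3K4me3, H3K27ac, P300 and PU.1) and an input control. Wild-type bone marrow-derived macrophages had these and MafB, with an input control. Alveolar macrophages had P300, PU.1 and an input control, and Maf-DKO macrophages with inducible Flag-MafB had H3K27ac, P300 and Flag. Each population and antibody had 1 library, so nothing was averaged and no test across samples was made.

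Per the submitters' processing notes, the tool named is Bowtie and the build is mm9. The version, the peak caller, its thresholds, the treatment of the input controls and the rule for comparing Maf-DKO with wild-type cells are not given in the sources used here. The values come from 3 deposited lists of the whole series, so per-library counts and depth were not analysed here and the depth is unknown. The H3K27ac list and the P300 list deposited by the authors each give a chromosome and a position, with start equal to end on every line. The third list, of self-renewal regions, gives start, end and a score per region. This score is the authors' own value, deposited with no unit, scale or header, and it was used only to describe and rank regions within that list.

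The design fixed before the data were examined assumed regions with widths and scores. Because the long lists hold positions alone, each position was given a window of 500 bp, the width of the P300 windows in the self-renewal list, for comparing the long lists with each other. Sharing at least 1 bp then means a distance below 500 bp, and sharing 25% or 50% means at most 375 or 250 bp. The comparisons of scores planned for the long lists could not be made, and the comparison of scores of overlapping and other regions was made within the self-renewal list. A region of that list counted as part of a long list when it held a listed position. To choose the regions to be named, a looser rule was used for P300 windows, which counted as overlapping the H3K27ac list when their centre was closer than 500 bp to a listed maximum, so that 500-bp windows share at least 1 bp. Regions of that list were split by width, as described with the results. Coordinates are those of the lists on mm9, with regions written as 1-based start and end and positions as given.

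Overlap was tested against 1000 random placements of each P300 position on its own chromosome, within the span occupied by the lists. The same placement was used for groups of positions. It was also run for regions of the self-renewal list, but is not reported as a test, because the name of that list describes it as drawn from the H3K27ac and P300 enhancers. Shares carry Wilson 95% confidence intervals. Differences of medians and correlations were tested with 100000 permutations, two-sided, and exactly where a group had fewer than 10 values. Chromosome shares were compared by a chi-square statistic with 100000 permutations of the list labels. Grouping positions at most 12.5 kb apart, joining regions up to 200 kb apart into loci, the distances between paired positions, the score correlation, the width comparison and the comparison of the short list with the rest of the P300 list were chosen after the data were seen. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 were used.

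The tests were tried on simulated data. With 30% of the 7323 P300 positions given a planted neighbour at 280 bp, the overlap test recovered a mean of 32.2% over 20 runs. A planted neighbour also counts for any other P300 position close by, and the randomly placed maxima can count too. How much each added was not counted. Without planted neighbours, 2 of 40 runs had p under 0.05. The test of medians found a shift of 1.5 SD in 38 of 40 runs with 43 values, and had p under 0.05 in 3 of 40 runs without a shift. These simulated values were independent and normally distributed, so the trial does not cover skewed scores or regions that share a locus. The test for groups of P300 positions found planted groups in 20 of 20 runs and none in 20 runs without them.

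Regions to be named were fixed before the data were examined as the 20 of highest score per long list, or the widest where there is no score, and the 30 of highest score in the self-renewal list that overlap both long lists. For the long lists the rule was applied to groups of positions, and the text names the leading ones. Genes were not assigned to regions. The gene table used here belongs to assembly GRCm38.p6 and the lists to mm9, and 14 H3K27ac positions on chromosome 1 lie beyond the last gene of that chromosome in the table. The table served only to look up the chromosome of genes in 9 fixed lists, of which 272 of 273 entries were matched. The planned tests of gene lists near regions and of sequence motifs were not run, since they need an annotation and a sequence of mm9. Alternatives were the required overlap, merging of windows, circular shift of each chromosome, autosomes alone, mean ranks and the middle 50% of regions by width, and further ones were added after the data were seen.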

Results

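The series profiled chromatin in mouse macrophages by ChIP-seq, in which DNA bound to a chosen protein or histone mark is precipitated with an antibody and sequenced. Maf-DKO macrophages lack the transcription factors MafB and c-Maf and can be kept growing in culture. They were profiled beside wild-type macrophages differentiated from bone marrow for 15 days, alveolar macrophages from the lung, and Maf-DKO cells carrying an inducible, Flag-tagged MafB. The 19 libraries comprised 16 immunoprecipitations and 3 input DNA controls, with 1 library for each population and antibody. There were therefore no replicates, and no difference between populations could be set against a replicate spread. The values analysed were 3 region lists of the whole series, given on mouse build mm9, and the sequencing depth behind them is unknown.

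A first comparison concerned where H3K27ac, an acetylation of histone H3 found at active enhancers and promoters, and P300, an acetyltransferase and coactivator bound at enhancers, were listed for Maf-DKO against wild-type macrophages. The H3K27ac list held 7489 positions and the P300 list 7323, each on 20 chromosomes. Every line gave a single position with neither width, score nor direction, so how many sites were gained or lost in Maf-DKO cells was not counted. The widest group of H3K27ac positions spaced at most 12.5 kb apart lay at chr16:10433920-10483005, with 6 maxima over 49.1 kb and 6 P300 positions inside it. The widest P300 group lay at chr17:8062110-8124147, with 11 P300 positions over 62.0 kb and 8 H3K27ac maxima inside it. An H3K27ac group of 7 maxima at chr17:8062429-8107727 covered part of the same stretch.

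Further wide H3K27ac groups were chr1:51550712-51596435 with 7 maxima, chr6:88877173-88922278 with 7 maxima and 6 P300 positions, and chr18:82662914-82707349 with 5 maxima and 5 P300 positions. Further wide P300 groups were chr6:113595036-113642692 with 10 positions and 5 H3K27ac maxima, and chr19:12509790-12553038 with 11 positions and 2 H3K27ac maxima. The P300 group with the most positions, singled out after its values were seen, held 13 at chr17:84489188-84525685, where 1 H3K27ac maximum was listed. The H3K27ac group with the most maxima, singled out in the same way, held 9 at chr17:45721502-45762209 beside 3 P300 positions. The P300 group at chr9:65383252-65416719 held 8 positions and 0 H3K27ac maxima. Of the 20 widest groups of each list, 20 H3K27ac groups and 19 P300 groups held a position of the other list.

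Both lists were clustered relative to random placement. Groups of 2 or more held 54.4% of P300 positions (Wilson 95% confidence interval 53.2 to 55.5%) and 42.9% of H3K27ac positions (41.8 to 44.1%). Random placement on the same chromosomes gave means of 7.52% and 7.66%, and no more than 8.96% and 8.84%, in 1000 draws (one-sided permutation p = 0.001 for each list, the smallest these draws can give). At a grouping distance of 5 kb the shares were 39.4% and 17.5%, against random means of 3.08% and 3.13%. Random positions covered whole chromosomes, so the excess includes any preference of a list for certain kinds of chromatin. Of the 3981 P300 positions in groups, 1863 had another within 2 kb. Spacings under 500 bp numbered 379 in the P300 list, while the smallest H3K27ac spacing was 554 bp, so the shares of the lists are not directly comparable. All intervals here cover counting error only, since neighbouring positions are not independent.

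P300 and H3K27ac were listed side by side at 49.0% of P300 positions, where 3589 of 7323 lay closer than 500 bp to an H3K27ac maximum (Wilson 95% interval 47.9 to 50.2%). Of the H3K27ac maxima, 44.9% had a P300 position as close (43.7 to 46.0%). A further 331 P300 positions had a maximum by 1 kb, and 2619, or 35.8%, lay over 5 kb from any. Random placement of the P300 positions on their own chromosomes gave 0.318% on average and at most 0.601% in 1000 draws (one-sided permutation p = 0.001, the smallest these draws can give). Random positions covered whole chromosomes, so the excess includes any preference of both lists for the same kind of chromatin. Requiring 50% of a 500-bp window to be shared, a distance of at most 250 bp, lowered the share to 13.6%. The wider regions of the self-renewal list, read below as H3K27ac regions, had a median width of 1854 bp. Distance to a maximum can therefore miss a P300 position that lies in the same acetylated region.

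The maxima lay beside the P300 positions and not on them. The median distance of the 3589 pairs was 285 bp (quartiles 246 and 327 bp), and 85.3% of pairs were from 200 to below 400 bp apart. Only 24 pairs, or 0.669%, lay within 100 bp (Wilson 95% interval 0.450 to 0.993%), where an even spread would put 20.2%. The maximum was at the higher coordinate in 1829 pairs and at the lower in 1760. H3K27ac maxima were listed on both sides within 1 kb of 41 P300 positions, 0.560% of the list, and no pair of H3K27ac maxima was closer than 554 bp. Whether the list keeps only 1 maximum per acetylated region is not stated. Within the self-renewal loci described below, however, 44 listed maxima fell in 44 wider regions, 1 in each. Those wider regions are read below as H3K27ac regions. The 0.560% therefore does not show that acetylation lies on 1 side only.

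**Figure D1:**
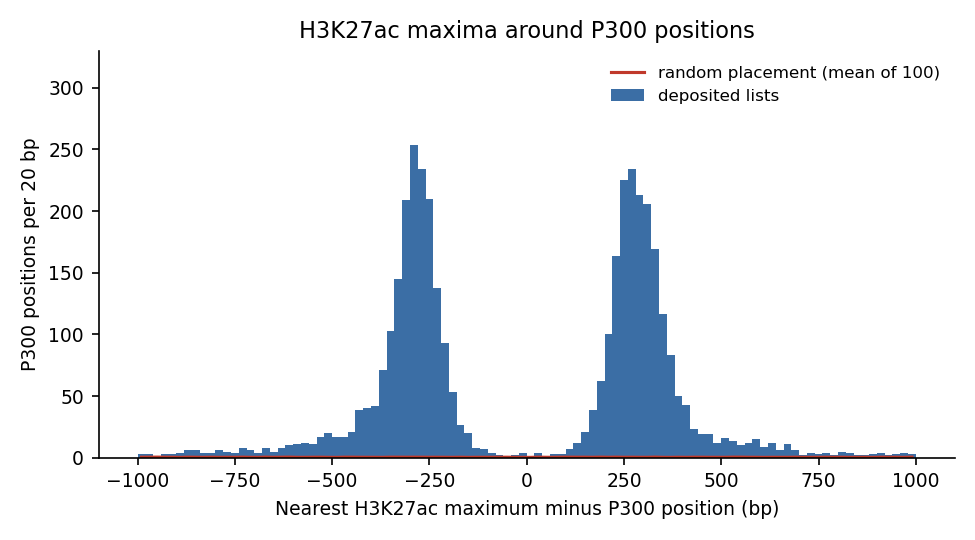
Distance from each P300 position to its nearest H3K27ac maximum, in bp (horizontal), against the number of P300 positions per 20 bp (vertical), with the mean of 100 random placements as a line. The pairs form a peak on each side of the P300 position, at a median distance of 285 bp, and 24 of 3589 pairs lie within 100 bp of it.

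The lists were spread over the chromosomes in similar shares. Chromosome 2 held the most positions in each, 9.51% of H3K27ac (Wilson 95% interval 8.86 to 10.2%) and 9.22% of P300 (8.58 to 9.90%), and chromosome X the fewest, 1.46% (1.21 to 1.75%) and 1.20% (0.976 to 1.48%). No difference between the lists was detected (chi-square = 14.3 on 19 degrees of freedom, p = 0.763, permutation test of the list labels). However, 49.0% of P300 positions lay closer than 500 bp to an H3K27ac maximum, and so on the same chromosome. The test treated all positions as independent, so it cannot tell whether the lists are spread alike apart from these shared sites.

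The short list addressed which of these sites belong to the self-renewal genes in the title of the series. It held 88 regions on 10 chromosomes, which fell into 16 loci when regions up to 200 kb apart were joined. Of the 88, 43 were windows of exactly 500 bp and 45 were wider, from 599 to 4420 bp with a median of 1854 bp. All 43 windows held a listed P300 position (Wilson 95% interval 91.8 to 100%), which was the centre of the window in 42, and 44 of the 45 wider regions, 97.8%, held a listed H3K27ac maximum (88.4 to 99.6%). The name of the list describes it as drawn from the union of the H3K27ac and P300 enhancers and as Maf-DKO only, the only direction that the lists state, so high membership was set by its making and is no test result. The windows are therefore called P300 windows below and the wider regions H3K27ac regions, a reading of their widths and positions and not a label in the list.

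Within the 16 loci the short list was complete with respect to the long lists. The spans from first to last region held 42 listed P300 positions and 44 listed H3K27ac maxima, and all of these were in the short list. In the 50 kb on either side of the spans, 10 more P300 positions and 5 more H3K27ac maxima were listed, around 5 of the loci, and the short list did not include them. Spans ran from 9.32 kb to 190.3 kb, with a median of 72.4 kb.

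The loci differed in their make-up. H3K27ac regions and P300 windows overlapped in 11 loci. The locus chr17:15757475-15912069 had the most regions, 7 of H3K27ac and 4 of P300, and each of its P300 windows lay in an H3K27ac region. The locus chr1:93082849-93133016 had 4 of each, all overlapping, and chr4:55635284-55644601 had 3 P300 windows in 2 H3K27ac regions. The locus chr15:61829824-61888449 had 3 H3K27ac regions and 2 P300 windows, of which 1 pair overlapped. Only P300 was listed at chr6:122495250-122604758, with 4 windows, and at chr8:74846358-74875076, with 3. Only H3K27ac was listed at chr10:82204516-82260272, with 2 regions. At chr7:97168030-97217165 and chr17:48432797-48518953 each class was present without overlap.

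**Figure D2:**
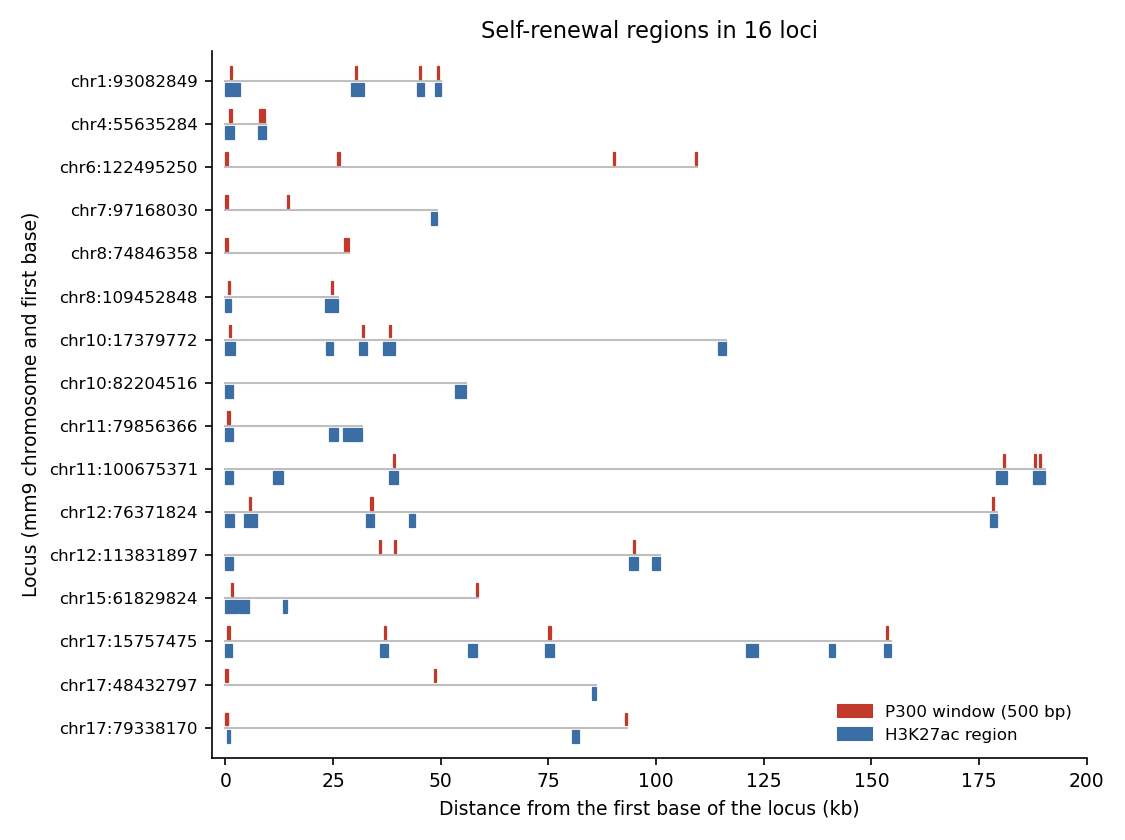
The 16 loci of the self-renewal list, each drawn to scale from its first base on mm9 (horizontal, kb), with P300 windows of 500 bp above the line and H3K27ac regions below it. H3K27ac and P300 overlap in 11 loci, and 2 loci have P300 windows only and 1 has H3K27ac regions only.

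Each region of the short list carried a score given by the authors, whose unit and scale are not stated. The scores ranged from 2.51 to 50.9 for P300 windows (median 5.64) and from 1.60 to 40.6 for H3K27ac regions (median 4.64). The highest P300 score, 50.9 at chr11:100714274-100714773, and the highest H3K27ac score, 40.6 at chr11:100713298-100715427, belonged to overlapping regions, yet no H3K27ac maximum was listed within this region. A set of 47 regions was counted as overlapping both long lists, namely H3K27ac regions that held a position of each list and P300 windows whose centre was closer than 500 bp to an H3K27ac maximum, which need not lie inside the window. Among these the highest scores were 22.7 for the P300 window chr17:15757947-15758446, 21.9 for the P300 window chr10:17417680-17418179, and 15.9 for the H3K27ac region chr17:15757475-15758933, which contains the first. They were followed by the P300 windows chr11:100864307-100864806 with 15.6, chr17:15794315-15794814 with 13.5 and chr12:113926471-113926970 with 13.3. The last of these lay in the H3K27ac region chr12:113925625-113927738 with 13.2, and chr1:93112020-93115022 followed with 11.6. The 30 highest comprised 18 P300 windows and 12 H3K27ac regions in 11 loci, down to a score of 4.92.

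P300 windows inside or overlapping an H3K27ac region scored higher than the others. The median score was 8.13 in 28 windows with such a partner and 3.70 in 15 without (two-sided permutation p = 0.0134, adjusted p = 0.0223 by Benjamini-Hochberg over the 5 tests of scores and widths within the short list). With 1 median per locus and class, in 11 and 7 loci, the difference of 3.62 no longer passed the threshold (exact permutation p = 0.149). Of these loci, 3 entered both groups, and the test did not pair them. Among H3K27ac regions the medians were 4.95 in 25 with a P300 window and 3.51 in 20 without, a difference that did not pass the test over all regions (permutation p = 0.102, adjusted p = 0.128). Compared within the 8 loci that hold regions of both kinds, those with a P300 window had the higher median in 6. The mean difference over all 8 loci was 2.19 (exact sign-flip permutation p = 0.0313, unadjusted). Leaving out any of those 6 loci raised the exact p to 0.0625, and without chr12:113831897-113932789, where the difference was 9.18, the mean was 1.20. Widths of 2026 and 1773 bp did not differ detectably either (permutation p = 0.195, adjusted p = 0.195).

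Across the 25 H3K27ac regions with a P300 window, the log2 scores of the 2 marks rose together, with Pearson's r = 0.617 (permutation p = 0.00138, adjusted p = 0.0069) and Spearman's rho = 0.499 (p = 0.0125, adjusted p = 0.0223). These are regions and not independent samples. Without the 2 regions farthest from the median P300 score, r was 0.257 (permutation p = 0.238) and rho 0.357 (permutation p = 0.0949), so neither passed the threshold without those regions. Without the site of highest score on chromosome 11 alone, r was 0.401 (permutation p = 0.0517) and rho 0.434 (permutation p = 0.0347), so the rank relation still passed. Over the means of 11 loci r was 0.509 (permutation p = 0.105) and rho 0.264 (permutation p = 0.435).

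**Figure D3:**
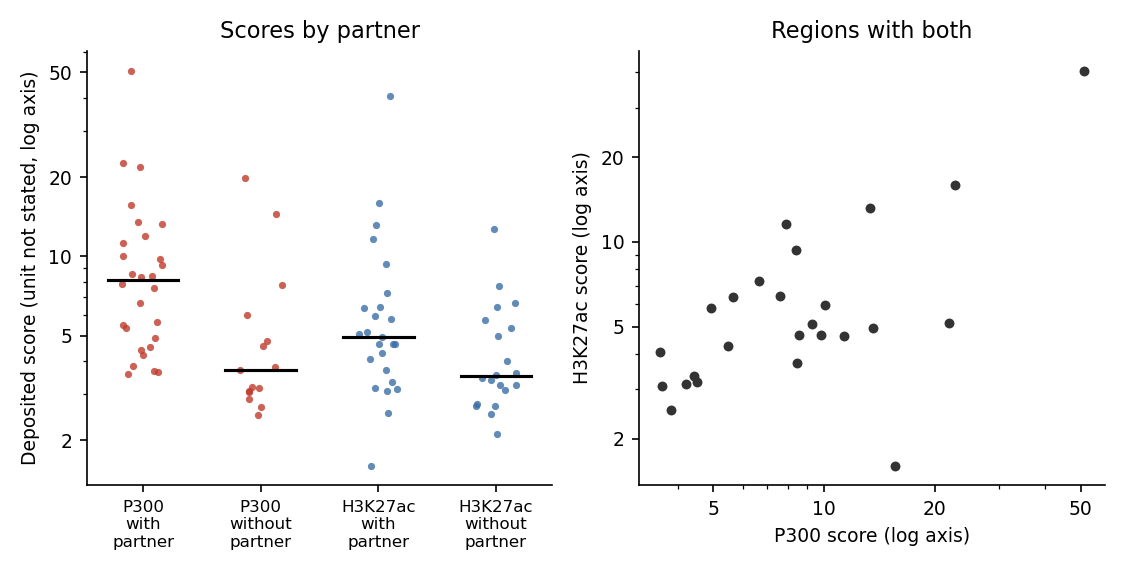
Deposited scores, of unstated unit, on log axes. Left, each point is a short-list region, grouped by class and by whether it overlaps a region of the other class, with the median as a line (8.13 and 3.70 for P300, 4.95 and 3.51 for H3K27ac). Right, the 25 H3K27ac regions with a P300 window, with the higher P300 score horizontally and the H3K27ac score vertically, where the point at the top right is the site of 50.9 and 40.6.

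P300 positions of the short list were near an H3K27ac maximum about as often as the rest of the P300 list. The shares were 22 of 42, or 52.4% (Wilson 95% interval 37.7 to 66.6%), and 49.0% of the other 7281 positions (47.8 to 50.1%), and no difference was detected (Fisher's exact test, two-sided, p = 0.757). The test treated positions as independent, although those of the short list share loci. Near meant closer than 500 bp to a maximum, which differs from overlapping an H3K27ac region. By overlap with a region of the short list, 28 of 43 P300 windows had a partner. No such regions are listed for the rest of the P300 list, so that measure could not be compared.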

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

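The alternatives at 5 and 25 kb, those that leave out a site or 2 regions, those that use 1 value per locus or compare within loci and the linking distances were chosen after the data were seen. The overlap of P300 with H3K27ac stayed above random placement in each of its 7 alternatives, with shares from 13.6% (50% of the window shared) to 64.2% (within 5 kb). The clustering of both lists stayed above random placement at 5 and 25 kb. Merging windows left 6944 P300 positions and changed nothing in the H3K27ac list, where no windows overlap. The chromosome distribution on autosomes alone gave a permutation p of 0.819, with the same limit from shared sites. The shares of the self-renewal list found in the long lists did not move. The number of loci was 23 when linked at 50 kb and 18 at 100 kb, and stayed at 16 from 150 to 1000 kb.

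The P300 score difference kept its direction and passed the threshold with mean ranks, with 50% overlap and without the site of highest score on chromosome 11. With 1 median per locus and class it was 3.62 and no longer passed, with 11 and 7 values in place of 28 and 15. The H3K27ac score difference did not pass the threshold in 5 of its alternatives, but did when compared within the 8 loci that hold both kinds of region, where the mean difference was 2.19 (exact sign-flip permutation p = 0.0313, and 0.0625 without any 1 of 6 of them). For P300, 3 loci held both kinds, too few to reach the threshold (smallest exact p 0.25). For the correlation of P300 and H3K27ac scores, Pearson's r no longer passed in any of the 3 alternatives. It was r = 0.401 without the site of highest score on chromosome 11, r = 0.257 without the 2 regions farthest from the median P300 score and r = 0.509 over locus means, where the number of values also fell. Spearman's rho still passed without the chromosome 11 site (0.434, permutation p = 0.0347) and did not in the others. The cause was not tested. Alternatives by score of the long lists, the score of self-renewal regions within the long lists, and the gene list and sequence alternatives were not run, because positions carry no score and mm9 annotation and sequence were not used here. The unknown depth limits any reading of a P300 position without H3K27ac, since a maximum below the authors' threshold would look the same.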

Other observations

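The tests of the distance pattern were chosen after it was seen, while those on groups of P300 positions and on density around the loci were written before their results, and the check without close neighbours was added afterwards. Genes could be placed by chromosome only, from assembly GRCm38.p6. Of the 51 genes in a fixed list of embryonic stem cell pluripotency and self-renewal genes, 32 (62.7%, Wilson 95% interval 49.0 to 74.7%) lie on the 10 chromosomes with self-renewal regions, against 54.1% of protein-coding genes. The other 8 fixed lists, among them cell cycle, macrophage and inflammatory genes and markers of other cell types, ranged from 45.5% to 63.6%. The 32 genes of the stem cell list include Klf4 on chromosome 4, Nanog on chromosome 6, Myc on chromosome 15 and Pou5f1 on chromosome 17. Sharing a chromosome assigns no region to a gene. The other 19 genes of the stem cell list, however, cannot share even a chromosome with a region of the self-renewal list. They include the pluripotency factor Sox2 on chromosome 3, Sall4 on chromosome 2, Klf5 on chromosome 14, Tbx3 on chromosome 5, and Zfx and Nr0b1 on chromosome X.

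In the gap between P300 positions and H3K27ac maxima, a fixed coordinate shift of a list would put the maximum on the same side of P300, but it was at the higher coordinate in 51.0% of pairs (Wilson 95% interval 49.3 to 52.6%). Imprecise placement around a shared centre would put at least 20.2% of pairs within 100 bp, but 0.669% were. A candidate explanation is that P300 sits in the nucleosome-poor centre of an acetylated region whose signal peaks on a flanking nucleosome. Over 24 regions of the self-renewal list, the median distance from the region's midpoint was 199.3 bp for the maximum and 145 bp for the P300 centre. Neither the median of the paired differences, 136.5 bp (permutation p = 0.384), nor their mean over 11 loci, 50.8 bp (exact permutation p = 0.439), passed, so this stays open, as does a rule in the making of the lists that would keep the positions apart.

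A hypothesis was that P300 positions in groups are more often beside an H3K27ac maximum than lone ones. By distance to a maximum the reverse was seen, with 47.0% against 51.3%, a difference of -4.30 percentage points (95% bootstrap interval over groups -6.81 to -1.75). Without P300 positions that have another within 2 kb the difference was -1.20 points (-4.12 to 1.70), and the excluded positions had a share of 43.5%. The measure may itself lower the share of close neighbours, since positions in the same region need not all be near its maximum. In the self-renewal list, 3 H3K27ac regions had 2 P300 windows. The maximum lay 527 and -281 bp from the window centres in chr4:55642793-55644601, and 1488 and 339 bp in chr11:100862785-100865680. In chr17:79338534-79339132 it lay 367 and 253 bp away. The difference is therefore not evidence that grouped positions are less acetylated.

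A further hypothesis was that the self-renewal loci are richer in listed positions than other places with a listed position. The median number of positions of both lists within 100 kb of the centre of the 16 loci was 5.5, at percentile 22.6 of 10000 random sets of listed positions (95% of which lay between 4 and 10), so no such enrichment was detected with 16 loci. The random places were centred on listed positions, which are often in groups, while the centre of a locus need hold none. The comparison may therefore lean against an enrichment and cannot exclude it.

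The H3K27ac region of highest score, at chr11:100713298-100715427, lies 26.0 kb from the nearest listed maximum, measured from its midpoint. The P300 window chr17:79338170-79338669, with a score of 8.57, is centred on no listed P300 position and has 1 at 114 bp from its centre. That position is the centre of an overlapping window, chr17:79338284-79338783, with a score of 3.68. Both windows were counted separately in the score comparison, each with a partner. Their partner, chr17:79338534-79339132, is 599 bp wide and starts at this P300 position. Its class, like that of the other regions, is a reading of width and position. Of the spacings between neighbouring P300 positions, 79 were from 100 to below 150 bp, 36 from 150 to below 200 bp and 8 from 50 to below 100 bp.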
